A study of Mus musculus with 454 samples.

How the data were processed

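The series holds 454 samples, 1 droplet library of nodose ganglion cells and 453 picked cells, all from C57BL/6 mice. Per the labels, tissue was dissociated with papain, collagenase and dispase, the droplet library was made with 10x Genomics reagents, and picked cells were amplified by Smart-seq2 and tagged with Nextera. The authors' processing notes list Cell Ranger 2.0.1 and the mouse build mm10; the aligner of the picked cells is not given in the sources used here.

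The deposited droplet matrices hold counts, UMIs per gene and barcode, for 28001 genes: 1 filtered matrix of 1108 barcodes and 1 raw matrix of 737280. The deposited table of the picked cells holds log2 values of reads for 36920 genes, with a floor at -5.64 that is the log2 of 0.02. Taken back to reads, 94.1% of the values above the floor were whole within 1 part in 1000. Values at the floor were read as 0 reads. Header lines of that table, written by the authors, give each cell a mouse and a target code. Of its columns 1 has no sample of that name and was left out, so 452 cells were used, and 53 cells from 4 mice carry the code na and enter no comparison of targets. The gene table and barcode file hold names only (unit other, per the file headers and the deposited matrices' sizes). Xist and Malat1 read 0 in the table and were not used.

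Droplet cells passed at 1000 UMIs and 500 genes. They were clustered in scanpy 1.11.5 on the log of counts per 10000 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1, and neurons again at 1.5 with list genes left out of the variable genes. Clusters were named by marker genes fixed beforehand and are called nodose-like or jugular-like. UMIs were summed per class or cluster and scaled by the total to CPM. Shares carry exact Clopper-Pearson intervals, sums exact Poisson intervals, and ratios the exact interval of a pair of Poisson counts, all at 95%. In 2000 simulated pairs at each of the ratios 1, 2 and 10 the last held the true ratio in 96.8%, 96.3% and 96.2% of cases. Counts of 0 allow 3 counts. Intervals and limits cover counting error only.

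Picked cells passed at 2000 genes, and a gene counted as detected at 10 reads. Each cell went to the 10x neuronal cluster with the highest Spearman correlation over 559 genes, up to 30 leading genes per cluster. Of 544 held-out 10x neurons 87.5% returned to their own cluster and 99.5% to their own class. Only the cluster profiles were held out, since the clusters and their leading genes came from all 10x neurons. That check stays within 1 protocol, so it does not measure the accuracy for picked cells.

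The design written before the data were examined assumed that no mouse or target was named. Tests across mice were added once the header lines had been read and before any gene was compared between targets. A mouse is the replicate: the mean over its cells of log2(CPM + 1), for 29 mice of at least 4 cells, entered 1 fit in limma 3.58.1 (R 4.3.3) with an intensity trend over the 7 codes, for 12713 genes with 10 reads in at least 5% of cells. Contrasts were the mean of both Gast codes against the mean of the 4 Int codes, Port against the mean of those means, GastG against GastP, IntL against the other Int codes, and an F test across the Int codes. P-values were adjusted over all genes by Benjamini-Hochberg at 0.05, and over each list alone where said. Lists were tested by camera with its preset correlation and with an estimated one. They were also tested by fry, which asks whether a list's own genes change and makes no comparison with other genes. EdgeR 4.0.16 with quasi-likelihood tests on summed reads was run beside limma. Shares of cells per mouse were compared by exact two-sided permutation tests, added after the shares had been seen. Mouse values were simulated from a normal distribution with each gene's mean and fitted spread, independently between genes and mice. With a log2 change of 1 in 100 of the genes, limma recovered 86% of them for Gast against Int and for Port. It recovered 58% for GastG against GastP, 62% for IntL and 45% across Int codes. At a change of 2 it recovered 100%, 100%, 91%, 97% and 94% in that order, with 6 to 12 unchanged genes called. On simulated counts, edgeR recovered 73% and 90% for Gast against Int at changes of 1 and 2.

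Of the 12 gene lists fixed beforehand (180 genes, 179 in the UMI gene table), 11 cover receptors, channels, peptides, transcription factors and the response to dissociation; the list of subtype genes holds names remembered from work on vagal afferents. In the droplet comparison the rule named, per list, the 2 highest and 2 lowest ratios among genes with 20 UMIs, and the 8 highest and 8 lowest outside the lists among genes with 200 UMIs and 20% of cells in a class. For targets it named every tested subtype gene, the 2 highest and 2 lowest of each list past the threshold, and the 8 highest and 8 lowest outside the lists. Gene models, mitochondrial and ribosomal protein genes were left out of the names outside the lists; mitochondrial ribosome genes, clone-named models and repeated symbols were left out as well, and class markers in the droplet comparison, both set after values were seen. Some genes that the rules pick are not reported here. Further members of lists, Tbx3 in the comparison of Gast codes, Sprr1a, Fos, Egr1 and Hspa1a by period and Apoe beside the glia markers are named outside the rule or were singled out after their values were seen. Coordinates come from GENCODE M21 on mm10, which matched 241 of 245 named genes by symbol, all with the identifier of the UMI gene table.

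Alternatives set before the data were examined changed cell filters, clustering settings, doublet removal (Scrublet), thinning, detection minimums and the matching. Those added after seeing the data were edgeR, weights by cells, a pseudocount of 10, other gene filters, all mice, each mouse of a small group left out, mice numbered up to 39 only, terms for that period, for the share of reads on satellite glia markers and for Ddx3y, the removal of 4 mice with high injury transcripts, centring of genes within a protocol and the raw barcodes. Ratios of thinned cells were used for genes with 20 UMIs and more than 3 in each class, a rule set after the values were seen. Figures were drawn with matplotlib 3.10.9; other steps used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.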

Results

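The series measured messenger RNA in single cells of the mouse nodose ganglion, which holds the cell bodies of the vagal sensory neurons that carry signals from the viscera to the brainstem. Its title places the work in the control of feeding. One part was a single droplet library (10x Genomics) of cells from whole ganglia of C57BL/6 mice aged 6 weeks, with 68051490 unique molecular identifiers (UMIs). The other part, called target-seq here, was a set of picked cells from mice aged 8 to 12 weeks, each sequenced as its own Smart-seq2 library. The deposited read table gives a mouse and a target code for each picked cell. The codes are GastG, GastP, IntP, IntM, IntD, IntL, Port and na, and the sources used here do not expand them. They are used as written, and Gast and Int stand for all codes that begin so. A median 10x cell held 55397 UMIs (range 13505 to 169263) and 7653 genes. All but 3 picked cells passed the gene minimum, with a median of 1617515 reads (range 3933 to 4692461) and 11389 genes. The coded cells numbered 60 from 5 GastG mice, 45 from 3 GastP mice, 45 from 4 IntP mice, 45 from 3 IntM mice, 35 from 3 IntD mice and 44 from 3 IntL mice, and the rest came from 9 Port mice or carried the code na. Median reads per cell ran from 1370327 in IntM to 1895909 in Port.

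The filtered cells of the droplet library, each with at least 13505 UMIs, were mostly neurons. Neurons made up 1087 of the cells (98.1%, exact Clopper-Pearson 95% interval 97.1 to 98.8) and satellite glia, the cells that wrap sensory neurons, made up 21 (1.90%, 1.18 to 2.88). The unfiltered matrix held 2468 barcodes of at least 1000 UMIs, of which 2435 were clustered. Neurons made up 47.8% of those 2435 and satellite glia 19.4%. A further 17.3% were left unnamed, in clusters of low UMIs with no marker of a class among their leading genes. Neuronal markers were the highest in some of these clusters, so the share of neurons may be higher. There was 1 library, so intervals here and in the next 2 paragraphs cover counting error only and no test was made.

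The question of the next comparison was how vagal neurons of the nodose type, which arise from placodes, differ from those of the jugular type, which arise from neural crest and express Prdm12. One of 28 neuronal clusters (number 8) carried the jugular markers. It held 47 neurons (4.32%, 3.19 to 5.71), at a median of 72828 UMIs against 55638 in the 1040 nodose-like neurons. Calca and Tac1, which encode the peptides CGRP and substance P, were 29.3-fold (28.2 to 30.5) and 45.2-fold (42.4 to 48.3) higher in the jugular-like neurons. Cckar, the receptor for cholecystokinin, was at 0.0730 times its nodose level in jugular-like cells (0.0578 to 0.0911), and the proton-sensing receptor Gpr65 at 0.0264 (0.00858 to 0.0618). Among list genes with enough UMIs, 45 were over 2-fold higher and 42 over 2-fold lower in the jugular-like cells. These counts, and those by list below, go by the ratio alone, whatever its interval. For some genes counted as lower the interval holds a ratio of 1. Examples are Trpv4 (0.00955 to 2.25), P2ry12 (0.00525 to 1.20) and Sprr1a (0.0403 to 1.245), on 1, 1 and 2 UMIs in jugular-like cells.

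The lists differed in direction. List members that are class markers, such as Htr3a, P2rx2, Prdm12, Prrxl1, Runx1 and Isl2, helped to define the classes and are not independent evidence. Of 7 itch genes measured, 5 were higher in jugular-like cells and 0 lower. Mrgprd was 723-fold higher (241.3 to 3557), but its UMIs lay in 8.51% of the 47 cells, and the serotonin receptor Htr1f was 11-fold higher. Of 11 genes of the neurotrophin and GDNF family receptor list 7 were higher and 2 were lower. That list also holds the cytokine receptors Il31ra, Osmr and Lifr. Among the higher were the artemin receptor Gfra3 at 82.6-fold (61.4 to 112.9) and Il31ra at 306.5-fold (114.1 to 1158, with UMIs in 10.6% of the 47 cells). Fibre type genes were higher in 8 cases and lower in 2 of 19: the sodium channel subunit Scn4b was 12.3-fold and the potassium channel Kcna1 6.66-fold higher. Of 12 mechanosensation genes 3 were higher, the ion channels Asic3 at 8.69-fold, Piezo1 at 6.53-fold and Piezo2 at 6.20-fold, and Tmc3 was lower at 0.0173 (0.00472 to 0.0444). Gut hormone and metabolite receptors went the other way, with 7 of 15 lower, Htr3a among them, and 2 higher. Transcription factors split, 7 of 21 higher (Prdm12 166.9-fold and Pou4f2 44-fold, in 10.6% of the 47 cells) and 9 lower (Tbx3 at 0.0460, Runx3 at 0.0472). Neuropeptides split as well, 5 higher and 5 lower of 14, with the natriuretic peptide Nppb 169.7-fold higher, in 4.26% of the 47 cells, and Vip at 0.0377. Of 11 TRP channels 2 were higher and 3 lower, with 0 UMIs of Trpc6 against a CPM of 3.03 in nodose-like cells, which allows at most 0.290 of the nodose level. Purinergic receptors were 3 higher and 2 lower of 10, with P2rx2, an ATP-gated channel and a nodose marker, at 0.103. Opioid and monoamine receptors were 2 higher (Htr1a, 21.2-fold) and 3 lower (the nicotinic subunit Chrna3 at 0.0910) of 11. Of 15 genes of the dissociation response 12 lay within 2-fold. The list of subtype genes, remembered from work on vagal afferents and partly chosen on these samples, is not independent evidence; 3 of its 22 members were higher and 11 lower. Outside the lists, Gna14 (88.9-fold) and Nptx1 (63-fold) were highest, and Dmkn (0.0148), Chst7 (0.0157) and the VEGF receptor Flt1 (0.0185) lowest, on 1, 1 and 3 UMIs in jugular-like cells. Cells thinned to 3000 UMIs left 27 list genes higher and 10 lower.

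**Figure D1:**
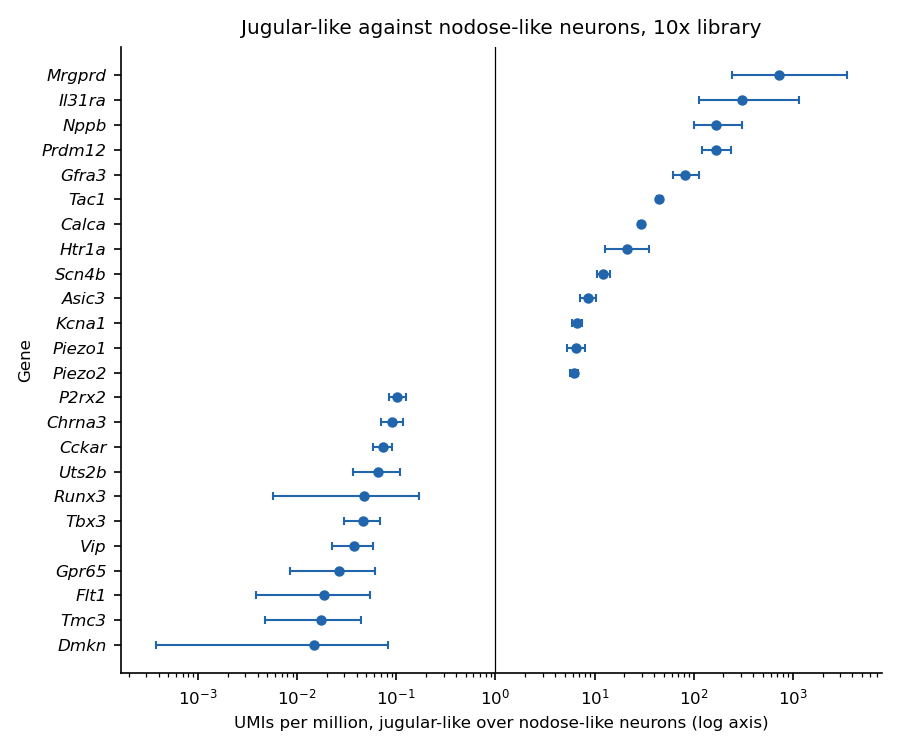
Ratio of CPM in 47 jugular-like over 1040 nodose-like neurons of the 10x library for named genes, on a log axis, with exact 95% intervals that cover counting error only. Mrgprd lies highest at 723 and Dmkn lowest at 0.0148.

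Gene groups were spread over the neuronal clusters in different ways. List genes took no part in the clustering. Of the list genes 57% had a UMI in at least 20% of neurons, and 22.9% did when cells were thinned to 3000 UMIs. Some marked single clusters. Cckar reached a CPM of 2087 (2048 to 2127) in cluster 0, which held 52.3% of its UMIs, and Uts2b, which encodes urotensin 2B, 651 there with 77.6% of its UMIs. Cluster 6 held 83.9% of the UMIs of Sst, the gene of somatostatin, and cluster 13 held 70.2% of those of Gpr65. Others were shared: cluster 16 held 27.7% of the UMIs of Vip, cluster 17 19.9% of those of the irritant receptor Trpa1 and cluster 23 25.9% of those of Piezo2. At least 1 UMI of Cckar lay in 83.4% of neurons and 28.6% of satellite glia, of Uts2b in 33.2% and 0%, of Gpr65 in 16.2% and 0%, and of Piezo2 in 30.5% and 33.3%, at median depths of 56119 UMIs in neurons and 14919 in glia. With 21 glia, 0% allows up to 3 counts. Glp1r, the receptor for the gut hormone GLP-1 (ENSMUSG00000024027, chromosome 17, 30901817 to 30940791, mm10), had 3 UMIs in all neurons and was seen in 0.184% of them (0.0223 to 0.663).

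At 10 reads, the jugular marker Prdm12 was detected in 3 picked cells. Other genes used as jugular markers were more frequent, Prrxl1 in 25.8% of cells, Runx1 in 40.3% and Isl2 in 99.8%. The nodose marker P2rx2 was found in 98.9% of cells, the cannabinoid receptor Cnr1 in 99.3%, the peptide gene Cartpt in 90.7%, the serotonin receptor Htr3a in 83.1%, Gpr65 in 41%, the peptide YY receptor Npy2r in 40.5%, Cckar in 40.1%, Trpa1 in 23.8%, Vip in 23.6%, Calca in 20.7%, Glp1r in 16.5%, the oxytocin receptor Oxtr in 15.8%, Sst in 12.5% and Uts2b in 8.24%. Of the gut hormone receptors, Gipr, Ghsr, Calcr and Gcgr were each in under 1% of cells at 10 reads, but Gipr was in 24.9% at 1 read. In all, 57% of list genes were found in at least 20% of cells, 72.6% at 1 read, 32.4% at 100 reads and 27.4% with cells thinned to 100000 reads.

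Some of these genes shared cells and others parted. Glp1r and Uts2b were found together in 33 cells, 5.41 times the 6.10 expected if they were independent, Oxtr and Uts2b at 3.93 times, Vip and Uts2b at 3.09 times, Glp1r and Oxtr at 2.65 times and Vip and Trpa1 at 2.49 times. Sst and Gpr65 shared 43 cells, 1.87 times the expected number. Gpr65 and Trpa1 shared 3 cells where 43.9 were expected. Oxtr and Sst shared 0 cells (exact upper limit 0.818%) where 8.86 were expected. These counts pool cells of all mice and carry no test.

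Matched to the 10x clusters by the correlation of 559 leading genes, most picked cells fell in few clusters. Cluster 13 (led by Gpr65 and Edn3) took 97 cells (21.6%) against 3.68% of 10x neurons, cluster 6 (Sst and Ctxn3) 88 cells (19.6%) against 4.51%, and cluster 19 (Mfap5, Lockd and Dbh) 68 cells (15.1%) against 3.04%. Clusters 4, 9 and 15 took 0 cells. Only 2 cells (0.445%, 0.0540 to 1.60) matched the jugular-like cluster, but 28 (6.24%) did when each gene was centred within its protocol, a step that left 67.5% of cells in the cluster they had.

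The matched types differed by target. Cluster 6 held 46% ± 18 (SD) of the cells of a Gast mouse and 4.03% ± 5.54 of those of an Int mouse (8 and 13 mice; exact two-sided permutation test over 203490 splits, p = 9.83e-06, adjusted over 5 clusters 4.91e-05; all 8 Gast mice lay above the Int median). Cluster 13 went the other way, at 3.58% ± 8.12 in Gast and 41.2% ± 25 in Int (exact adjusted p = 0.00139, 8 of 8 Gast mice below the Int median). Cluster 19 was at 5.14% in Gast and 25.3% in Int (exact adjusted p = 0.0446, 7 of 8), and was highest in IntP at 54.4% ± 23 (4 mice). Clusters 0 and 1 did not pass (exact adjusted p = 0.0775 and 0.177, lower in 7 of 8 Gast mice each). These 5 clusters, the fullest of 28 among picked cells, were taken after the shares had been seen. The adjustment does not cover the other clusters. It leaves the call for cluster 19 uncertain, as its exact permutation p before adjustment was 0.0267. Among mice numbered up to 39, with 4 Gast mice, cluster 6 differed by 56.6 points (exact adjusted p = 0.00210), cluster 13 by -41.2 (0.0158) and cluster 19 by -23.2 (0.120).
The share of cells with Calca was 35.8% ± 10.8 in Gast and 10.5% ± 5.63 in Int mice (exact adjusted p = 3.93e-05 over 8 genes, 8 of 8 Gast mice higher), and that with Gpr65 was 34.4% ± 9.73 and 60.3% ± 22.5 (exact adjusted p = 0.0241, 8 of 8 lower; 0.293 within mice up to 39). The shares with Glp1r were 15.8% ± 6.57 and 16.5% ± 11 (exact adjusted p = 0.871, 4 of 8 below the Int median), and those with Oxtr, Sst, Vip, Uts2b and Trpa1 did not pass either (exact adjusted p = 0.749, 0.235, 0.795, 0.314 and 0.0751).

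**Figure D2:**
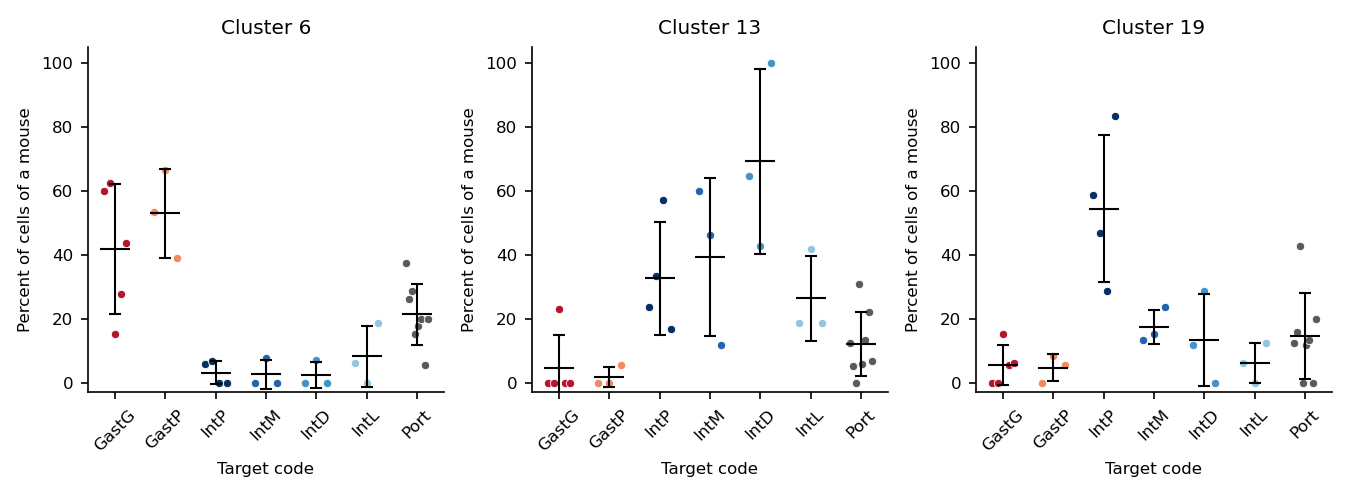
Percent of each mouse's cells matched to clusters 6, 13 and 19 by target code, 1 point per mouse with at least 4 cells, with the mean and SD of mice. Cluster 6 averaged 46% in Gast and 4.03% in Int mice.

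Cells with a Gast code were set against cells with an Int code. Both subunits of the serotonin-gated channel were far lower in Gast: Htr3a (ENSMUSG00000032269, chromosome 9, 48899213 to 48911099) by -5.29 ± 0.58 on the log2 scale (SE, 8 Gast and 13 Int mice, adjusted p = 2.38e-07, lower in 8 of 8 Gast mice than the Int median) and Htr3b by -4.16 ± 0.52. Calca (ENSMUSG00000030669, chromosome 7, 114631478 to 114636357) was higher in Gast by 2.65 ± 0.30 (adjusted p = 3.09e-07, 8 of 8), and so was Gfra1, the receptor for GDNF (ENSMUSG00000025089, chromosome 19, 58235604 to 58455909), by 3.51 ± 0.46 (3.54e-06, 8 of 8). The nicotinic subunit Chrna3 (ENSMUSG00000032303, chromosome 9, 55010111 to 55026562) fell by 3.26 ± 0.31 (3.28e-08, 8 of 8). In all, 1151 genes were higher in Gast and 727 lower of 12713 tested by limma across mice. Each value is a mean over all cells of a mouse, and the mix of matched types differed by target. A change may therefore reflect that mix rather than a change within a type of neuron. No comparison within a matched cluster was made, here or for the other targets below. With mice up to 39 alone these changes were -5.85 for Htr3a, 2.95 for Calca, 4.27 for Gfra1 and -3.45 for Chrna3.

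Of 16 gut hormone and metabolite receptors 2 rose in Gast and 5 fell (3 and 5 adjusted over the list alone). Npy2r rose by 0.98 and the prostaglandin receptor Ptgfr by 1.06. Cells with Npy2r averaged 49.3% in IntL mice, between GastG (44.6%) and GastP (51.5%), and 8.18% to 33.2% in the other Int codes. Beside both serotonin subunits, Gpr65 fell by 2.72, and the fatty acid receptor Ffar3 and the secretin receptor Sctr fell too. The opioid and monoamine list had 3 falls and 1 rise of 11 (4 and 2 adjusted over the list alone): the kappa opioid receptor Oprk1 fell by 2.69 and Chrnb4 fell with Chrna3, while Htr4 rose by 0.73. Genes of the neurotrophin and GDNF family receptor list rose in 5 of 10 cases, the cytokine receptor Lifr among them. They fell in 2 (6 and 2 over the list alone), with Ntrk2 at -0.90 and Ngfr at -0.53. Of 11 mechanosensation genes 4 rose and 1 fell (4 and 2 over the list alone): Asic1 rose by 1.28, the potassium channel Kcnk2 by 1.20 and Piezo2 by 0.71, and Tmc3 fell by 2.54. TRP channels rose in 4 cases and fell in 1 of 11 (5 and 2 over the list alone), with the heat and capsaicin receptor Trpv1 up by 1.69 and Trpc4 at -1.54. Fibre type genes rose in 5 and fell in 1 of 17 (6 and 1 over the list alone), among them Kcna1 at 1.73 and the calcium buffer Calb1 at -1.06. Neuropeptides had 2 rises and 1 fall of 11 (4 and 1 over the list alone), with neuromedin B (Nmb) at 1.66 and Uts2b at -0.87. Purinergic receptors had 1 of each among 10 (P2ry14 at 0.96, P2rx2 at -1.41; 1 and 1 over the list alone). Transcription factors rose in 4 and fell in 2 of 14 (5 and 2 over the list alone), Pou4f1 by 1.20 and Tbx3 by -2.34. The itch list had 1 of each among 6 (S1pr1 at 1.34, Il4ra at -1.16; 1 and 2 over the list alone). Of 14 dissociation genes 4 rose and 0 fell (6 and 0 over the list alone), with Jun at 1.46 and Egr1 at 1.01; without 4 mice of high injury transcripts (Port 21, 22 and 27, and GastP 44, which is in this comparison) 2 rose and 1 fell. Subtype genes rose in 7 and fell in 3 of 21 (9 and 3 over the list alone, not independent evidence): the reprimo gene Rprm rose by 2.57 and Gda by 1.79, Edn3 fell by 1.54, and Glp1r differed by -0.20 (adjusted p = 0.652) and Oxtr by -0.05 (0.919).
Outside the lists the highest changes were those of S100a6 (4.09), Lgi1 (4.08), Klhdc8a (4.05) and Ctxn3 (3.93), and among the lowest were those of Tmem54 (-4.36), Nnat (-4.05), Nsg1 (-3.37) and the calcium channel gene Cacna1e (-3.06), each in 8 of 8 Gast mice. No list passed camera's test against other genes (lowest adjusted p = 0.111; 0.264 with an estimated correlation). Fry, which makes no comparison with other genes, passed some lists. Higher in Gast were neurotrophin and GDNF family receptors (fry adjusted p = 0.000268), subtype genes (0.0008975, not independent evidence), neuropeptides (0.0104) and dissociation genes (0.0352). Lower were opioid and monoamine receptors (fry adjusted p = 0.00393) and gut hormone receptors (0.00779). Markers of satellite glia had 0 of 6 genes past the threshold, at a median of 0.00, while 3 of 5 nodose-like markers were lower (median -0.64) and 2 of 3 jugular-like markers higher (median 0.82). Of 4 sympathetic-like markers 1 was higher and 1 lower, and 1 of 2 red blood cell markers was higher (median 0.46). All Int mice have numbers up to 39, and the 4 earlier Gast mice held the Y-linked gene Ddx3y while the 4 later ones did not.

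**Figure D3:**
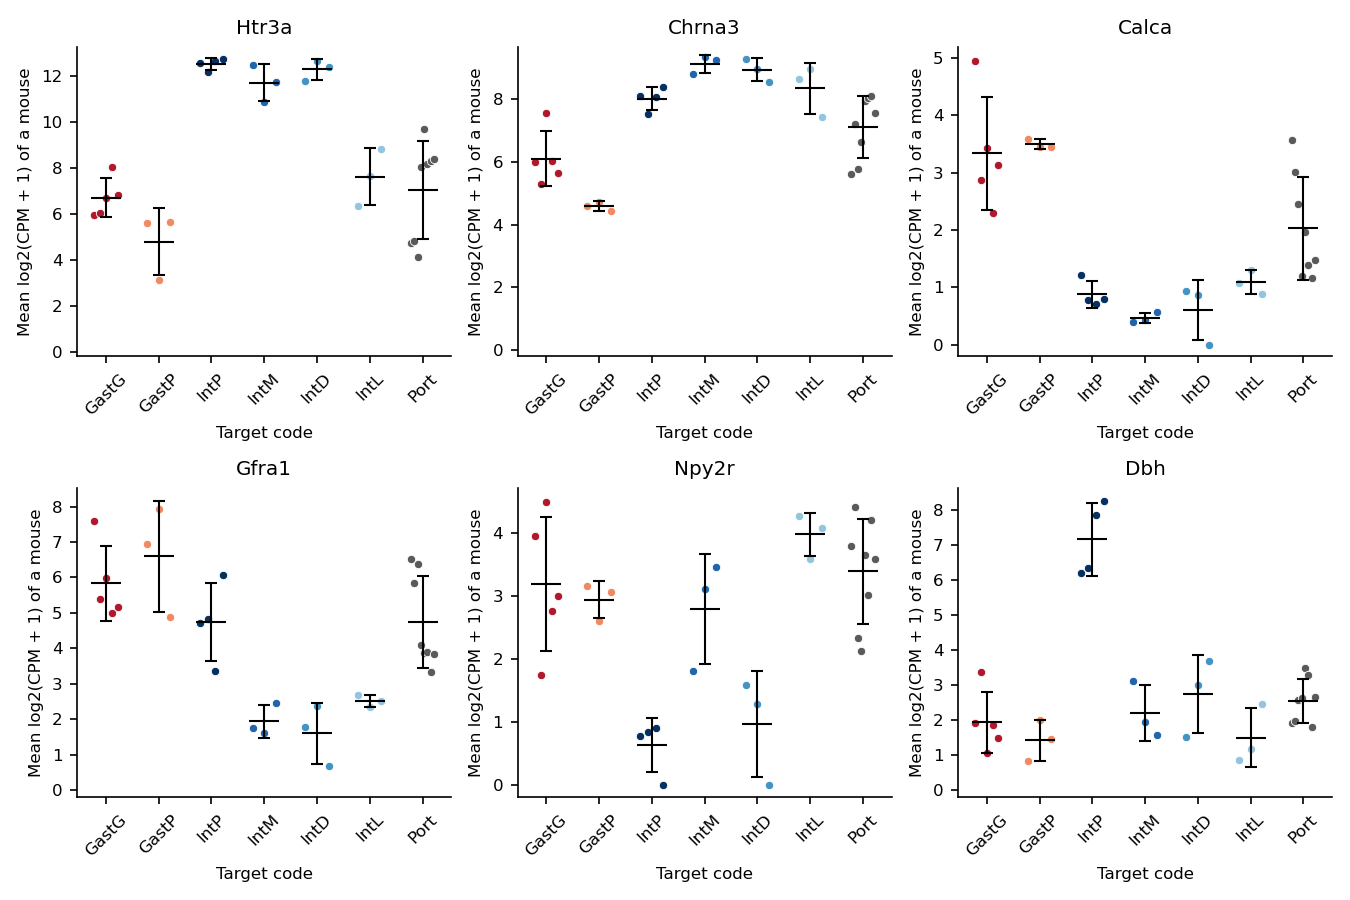
Mean log2(CPM + 1) per mouse of 6 genes by target code, 1 point per mouse with at least 4 cells, with the mean and SD of mice. Htr3a averaged 12.5 in IntP and 7.62 in IntL, and Dbh 7.15 in IntP and 2.21 in IntM.

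Both Gast codes were compared with each other. Of 12713 genes 0 passed in limma, 550 had an unadjusted p under 0.05, and edgeR called 0 as well. Tbx3 was the gene of lowest p, at 1.95 ± 0.37 (5 GastG and 3 GastP mice, limma adjusted p = 0.154). Calls appeared without the gene filter (2), among mice up to 39 (6), without 4 mice of high injury transcripts (Port 21, 22 and 27 and GastP 44; 28), without GastP mouse 44 alone (15) and without GastG mouse 7 or 43 (1 each). The dissociation list passed camera as higher in GastG with its preset correlation (adjusted p = 0.0276) and not with an estimated one (camera adjusted p = 0.526). Of its 14 genes 0 were past the threshold, and it did not pass fry (adjusted p = 0.887).

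The Int codes differed among themselves in 1252 of 12713 genes (9.85%) by limma's F test. Dbh, the enzyme that makes noradrenaline (ENSMUSG00000000889, chromosome 2, 27165233 to 27183200), led with 7.15 ± 1.04 in IntP (mean log2(CPM + 1) of mice and SD, 4 mice) against 2.21 ± 0.80 in IntM and 2.74 ± 1.10 in IntD (3 mice each, and lowest in IntL, adjusted p = 2.77e-06). The mechanically gated channel Piezo1 was also highest in IntP, at 4.77 ± 0.65 against 1.65 ± 0.55 in IntM (0.000708), as were the leukotriene receptor Cysltr2 (6.79 against 2.99 in IntL) and Gfra2 (6.14 against 3.20). Npy2r was highest in IntL at 3.98 ± 0.35 and lowest in IntP at 0.63 ± 0.43 (0.000780), and Cckar ran from 4.68 ± 1.15 in IntL to 0.89 ± 0.94 in IntP (0.00305). IntM held the highest levels of Kcnk2 (5.09 ± 0.51, 0.00395), Uts2b (2.73 ± 0.81, 0.0143) and Sctr (1.43, 0.0224). Adora1, the adenosine A1 receptor, ran from 6.71 in IntP to 4.19 in IntD. By list, 6 of 16 gut hormone receptors, 5 of 11 mechanosensation genes, 4 of 10 neurotrophin and GDNF family receptors, 4 of 14 dissociation genes, 2 of 17 fibre type genes, 2 of 11 opioid and monoamine receptors, 1 each of neuropeptides, purinergic receptors, transcription factors and itch genes, 0 of 11 TRP channels and 7 of 21 subtype genes changed. Adjusted over the list alone these counts were 8, 5, 5, 6, 7, 3, 1, 1, 0, 1, 0 and 12 in that order. Glp1r did not pass (adjusted p = 0.223). The percent of genes was 3.11 with the glia share of reads as a term and 6.28 with mice weighted by cells. It was 4.37 without IntL mouse 33, 6.10 without IntL mouse 34, and 4.80, 4.65 and 4.33 without IntP mouse 11, 16 or 17. Without the 4 mice of high injury transcripts it was 16.2.

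IntL was set against the other 3 Int codes. Its mice carry the numbers 33, 34 and 39 and the other Int mice 11 to 26, so the target cannot be told apart from the order of the mice. Htr3a and Htr3b were lower in IntL by -4.55 ± 0.83 and -4.01 ± 0.75 (log2, SE; 3 IntL and 10 other mice; adjusted p = 0.00144 and 0.00180; 3 of 3 IntL mice below the others' median), and Ret, the signalling receptor for GDNF ligands, by -1.77 ± 0.26 (0.000149, 3 of 3). Npy2r (2.52 ± 0.48, 0.00194) and Cckar (2.51 ± 0.61, 0.0151) were higher in 3 of 3. In all 3.04% of the 12713 genes were higher and 2.47% lower by limma (701 genes), and 5.57% and 2.86% by edgeR. Markers of satellite glia moved with IntL: they took 0.189% to 0.285% of reads in its mice against 0.0152% to 0.119% in the other Int mice, their median change was 1.65, and 1 of the 6, the lipid carrier Apoe, passed with a rise of 3.05. Gut hormone receptors rose in 2 and fell in 2 of 16 (3 and 4 adjusted over the list alone). Of 14 dissociation genes 4 rose, Egr1 by 1.77, Dusp1 by 1.22, and Fos and Junb, and 0 fell (4 and 0 over the list alone). That list passed camera with its preset correlation (adjusted p = 0.00305) and not with an estimated one (camera adjusted p = 0.531). It passed fry (adjusted p = 0.0358). Subtype genes rose in 4 (Rprm 2.39, Eya1 2.14, Gda 1.62, Npy2r) and fell in 2 of 21 (Cysltr2 -2.17, Edn3 -1.75; 5 and 3 over the list alone, not independent evidence). P2ry12, an ADP receptor, was the 1 purinergic gene of 10 to rise, by 0.88 (2 and 1 over the list alone). Ret was the 1 fall of 10 neurotrophin and GDNF family receptors (0 and 2 over the list alone) and Cysltr2 that of 6 itch genes (0 and 1). Mechanosensation, TRP, neuropeptide, fibre type, transcription factor and opioid lists had 0 genes past the threshold by limma of 11, 11, 11, 17, 14 and 11 (over the list alone 0, or 1 fall for mechanosensation). Outside the lists Fxyd6 (3.48), Itm2a (3.38), Moxd1 (2.89) and Th, the first enzyme of catecholamine synthesis (2.85), were beside Apoe among the genes that rose most. Syt2 (-3.36), Nxn (-3.05), Avil (-2.82) and Dicer1 (-2.65) were among those that fell most. With the glia share as a term 1.18% of genes passed and the changes were -3.79 for Htr3a (adjusted p = 0.0452), -3.22 for Htr3b (0.0573), 2.83 for Npy2r (0.0107), 2.39 for Cckar (0.118) and 0.74 for Apoe (0.675); 1 of 14 dissociation genes then rose. Against 5.51% with all mice, 0.842% of genes passed without IntL mouse 33 and 2.74% without mouse 34.

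The Port cells were set against Gast and Int together. In Port, Rprm was higher by 1.56 ± 0.25 (log2, SE; 8 Port and 21 other mice; adjusted p = 0.00262; 8 of 8 Port mice above the others' median), and so were Gal, the gene of the peptide galanin, by 1.66 ± 0.49 (0.0480, 8 of 8), Gpr151 by 2.18 ± 0.62 (0.0403, 8 of 8), Ecel1 by 2.42 ± 0.71 (0.0472, 6 of 8) and Sox11 by 1.88 ± 0.56 (0.0490, 7 of 8). Sprr1a, Atf3 and Gap43, which are known from injured sensory neurons as Gal is, did not pass (2.77, 1.53 and 0.43; adjusted p = 0.0517, 0.0994 and 0.0890). Lower in Port were Scn10a, the sodium channel of nociceptors, by -1.25 ± 0.31 (0.0261, 8 of 8), Kcna2 by -1.29 ± 0.27 (0.0135, 8 of 8), the transcription factor Isl1 by -0.87 ± 0.18 (0.0114, 8 of 8) and Gpr65 by -1.75 ± 0.47 (0.0333, 8 of 8). In all 2.05% of the 12713 genes were higher and 2.95% lower by limma (635 genes).

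Many of these calls were lost when a few mice were left out. Port mice 21, 22, 27 and 28 carry numbers up to 39, and Sprr1a was high in them. Sprr1a (ENSMUSG00000050359, chromosome 3, 92483952 to 92485895) averaged 5.60, 9.42, 7.77 and 5.58 there and 0.17 to 3.12 in the 5 later Port mice. Against Gast mice of the same period, the 3 Port mice up to 39 with enough cells had 3086 changed genes, and those above 39 had 1, P2rx2, by limma; the difference of both contrasts passed for 1713 genes. The genes past the threshold for Port against Gast and Int were 1.08% of those tested without 4 mice of high injury transcripts, 1.92% without GastP mouse 9, 1.05% without GastP mouse 10, 10.9% without GastP mouse 44, and 9.57% (4.92% higher, 4.65% lower) with the period as a term. EdgeR gave 4.56% higher and 1.38% lower. Without the 4 mice Rprm (1.26), Cckbr (1.59) and Scn10a (-0.97) still passed, and Gal (0.99), Gpr151 (0.60), Ecel1 (0.58), Sox11 (0.77), Kcna2 (-0.77), Isl1 (-0.49), Gpr65 (-1.28), Cysltr2 (-1.51) and Chrnb3 (-1.92) did not. With Ddx3y as a term Gal (1.53), Gpr151 (2.10), Ecel1 (2.36), Sox11 (1.77) and Cysltr2 (-1.28) kept most of their change and did not pass.
By list, dissociation genes rose in 2 of 14 (Sox11, Jun 1.09) and fell in 0 (6 and 0 adjusted over the list alone); the list passed camera as higher (adjusted p = 0.0208; adjusted p = 0.614 with an estimated correlation), and 0 of its genes passed without the 4 mice. Transcription factors fell in 3 of 14, among them Isl1 and Isl2 (8 over the list alone). They passed camera as lower with its preset correlation (adjusted p = 0.0112) and not with an estimated one (camera adjusted p = 0.604). Fry passed transcription factors (adjusted p = 0.00774) and itch genes (0.0277) as lower, and did not pass the dissociation list (0.135). Gut hormone receptors fell in 3 of 16 (Htr3b, Gpr65, Cnr1; 4 rose and 4 fell over the list alone), and Htr3b, at -2.18 in limma, was at 0.13 in edgeR. Fibre type genes fell in 3 of 17 (3 over the list alone), neurotrophin and GDNF family receptors rose in 1 and fell in 2 of 10 (Gfra3 0.88, Gfra2 -1.46, Ngfr -0.67; 1 and 2), Trpv2 (0.23) was the 1 of 11 TRP channels to rise (1 over the list alone) and Gal the 1 neuropeptide of 11 (2 and 1). Cysltr2 (-1.35) was the 1 itch gene of 6 and Oprk1 (-1.19) the 1 opioid or monoamine receptor of 11 to fall (1, and 2 with 1 rise). By limma 0 of 11 mechanosensation and 0 of 10 purinergic genes passed (1 fall each over the list alone). Subtype genes rose in 1 (Rprm) and fell in 3 of 21 (Chrnb3 -2.12, Gpr65, Cysltr2; 3 and 4 over the list alone, not independent evidence). Outside the lists Cckbr (2.64), Sema6a (2.11) and Adam8 (1.86) rose, and Dcdc2a (-2.15), Chrna6 (-1.95) and Olfm3 (-1.89) fell. With the glia share of reads as a term 0.747% of genes passed, among them Rprm (1.45, adjusted p = 0.00974), Cckbr (2.43), Kcna2 (-1.23) and Isl1 (-0.83), while Gal was at 1.34 (adjusted p = 0.121).

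**Figure D4:**
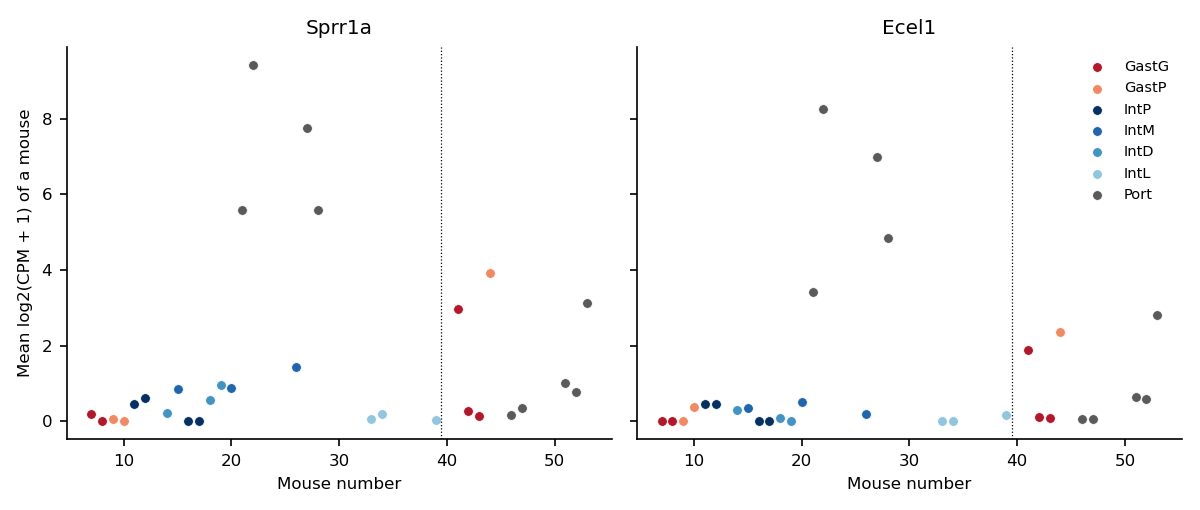
Mean log2(CPM + 1) of Sprr1a and Ecel1 per mouse against the mouse number, coloured by target code, with a dotted line after mouse 39. Sprr1a reached 9.42 in Port mouse 22 and lay between 0.17 and 3.12 in Port mice numbered above 39.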

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

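The tests in this part were chosen after the results they measure had been seen, except that of glial genes among those higher in IntL.

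Port mice differed by period: the contrast of Port with Gast changed between mice numbered up to 39 and above 39 in 1713 genes. Sprr1a stood 7.53 log2 units higher in Port than in Gast among the earlier mice, with Ecel1 at 6.12, Sdc1 at 5.76 and Atf3 at 4.26. The tables argue against RNA from glia, since IntL mice with a mean glia share of 0.230% of reads against 0.174% held Sprr1a at no more than 0.19. They also argue against a few extreme cells (73.8% of the cells of mice 21, 22 and 27 had Sprr1a, interval 58 to 86.1) and against sex read from Ddx3y (present in 2 of the 4 Port mice with high Sprr1a). The target code is the same in earlier and later Port mice, so no test of the target was made. For Sprr1a, later Port minus later Gast was -0.74 ± 0.64, but GastG mouse 41 (2.98) and GastP mouse 44 (3.91) raise that reference. A response to dissociation cannot be told apart. Of 14 dissociation genes 28.6% (Sprr1a, Atf3, Sox11 and Jun) were higher by over 1 log2 unit in the earlier Port mice. That share cannot decide, because Sprr1a, Atf3 and Sox11 belong to the pattern itself, which leaves Jun alone. The median change of Fos, Egr1 and Hspa1a was 0.29. Injury of the axons or handling of those mice may account for it and stays open, since the labels say nothing of either.

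IntL cells carried more glial RNA. Of the genes higher in IntL, 37.3% (interval 32.4 to 42.4) had at least 2 times the level in satellite glia than in neurons of the 10x library, against 19.5% of all genes tested and 5.69% of those lower in IntL. For that set as a whole, glial RNA in the picked cells and a change within neurons cannot be told apart, because the share lies between the bounds set beforehand and glial share goes with the target in all 3 IntL mice. With the glia share as a term Htr3a and Htr3b were still lower, and the smaller fall was -3.22. Htr3b then missed the threshold (limma adjusted p = 0.0573). Because the glial share goes with IntL among the Int mice, the term cannot settle whether glial RNA accounts for these falls. A difference between targets stays open as the biological explanation, and so does the order of the mice, since IntL mice are numbers 33, 34 and 39 and the other Int mice 11 to 26; a term for the period, split at 39, cannot separate them.

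Glp1r was seen in 0.184% of 10x neurons and 16.5% of picked cells. Depth is not the whole cause, since cells thinned to 50000 reads held a Glp1r read in 13.6% of cells (interval 10.6 to 17.1). A richer supply of such cells among those picked does not account for it either: Uts2b and Oxtr, found with Glp1r, were 1.59 and 0.876 times as high in picked cells as in 10x neurons where Glp1r was 190.1 times (65.1 to 922), so the higher of both ratios was 0.838% of that of Glp1r. How the 3' protocol counts this gene and the ages of the mice may contribute and were not tested.

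Single mice lay far from the others of their target in 35 groups (8.60% of those tested). The rule cannot be applied to 3 mice, so GastP, IntD, IntM and IntL were not tested. For Bmp3, Gfra3, Mc4r, Piezo2, Ptgfr and cluster 0 in IntP and for cluster 13 in GastG the other mice were at 0, so any level above 0 would stand out there, and the 5% that the rule gives by chance does not hold for such values. In GastG, mouse 41 had high Sprr1a (2.98), Ecel1 (1.88), Sox11 (3.91), Tnfrsf12a (2.17) and cluster 13 cells (23.1%). GastG mouse 7 had high Sst (3.18), Moxd1 (2.54), Ntsr1 (3.87) and P2ry14 (2.09), and mouse 43 high Rprm (5.54). In IntP, mouse 17 had high Bmp3 (1.12), Fam150b (1.88) and Piezo2 (0.89) and no Npy2r (0.00). IntP mouse 12 had high Epha5 (1.93), Nmb (3.52) and Ptgfr (0.23) and low Cacna1e (6.08) and Syt2 (6.92). IntP mouse 11 had high Gfra3 (0.34), Mc4r (0.20) and cluster 0 cells (5.88%), and mouse 16 high Ntsr1 (6.00), Oxtr (0.44) and Sox11 (3.96). In Port, mouse 22 had high Il4ra (5.32), Mc4r (1.81), Nsg1 (9.13) and cluster 0 cells (21.1%) and low Itm2a (1.52) and Th (0.74). Port mouse 21 had high Pou4f1 (6.19), mouse 46 Htr4 (0.92), mouse 47 Maob (7.14) and mouse 27 cluster 19 cells (42.9%).

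In data outside the comparisons, tdTomato had 81 UMIs in the 10x library, found in 6.90% of neurons, while sequences of GFP and mCherry had 0. Of 2468 barcodes of the raw matrix with at least 1000 UMIs, 2435 were clustered. Those 2435 included 6.32% like myelinating Schwann cells, 5.13% like endothelial cells, 2.38% like mural cells, 0.821% like fibroblasts and 0.821% like macrophages, and 17.3% were left unnamed.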

How the results depend on the processing

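All alternatives for comparisons of targets were chosen after seeing the data; those of the 10x and cell-share values were planned, except the raw barcodes, the centred matching and the mice up to 39. For genes named by target, 2254 of 2525 values kept their direction and side of the threshold, 9.46% fell short of it, 31 passed newly and 1 reversed; with mice left out in turn 4599 of 4935 kept both, 6.53% fell short and 14 passed newly. Of the values of the 10x library, shares and matching 67.4% stayed within their error and 31.1% moved. The jugular-like share of 4.32% was 2.58% with 1000 variable genes and 15 components, 2.30% at 2 times the resolution and 2.95% by a rule per cell. Neurons were 47.8% of the clustered raw barcodes, a set that includes shallower cells and the unnamed 17.3%. Thinning to 3000 UMIs gave 27 higher and 10 lower list genes and 41 in 20% of neurons, and Hrh1 (log2 0.07) was at -0.23 as a mean over cells. List genes in 20% of picked cells were 58 at 100 reads and 49 when thinned; depth limits these counts. Jugular-like picked cells were 6.24% with centred genes and 0% by Prdm12. The next values are percents of the genes tested. Gast against Int gave 10.9 to 15.2 with mice left out in turn. With no gene filter, and so over 18698 genes, Gast against Int fell from 14.8 to 9.66 (1806 genes), IntL to 3.10 (580) and the Int codes to 4.76 (890). Port against the rest (5.0) gave 3.11 with weights by cells, 1.01 with no gene filter, 8.35 with all mice, 28 up to mouse 39, 9.57 with a term for the period, 0.747 with one for glia, 1.08 without 4 mice of high injury transcripts, and 1.05 (without GastP mouse 10) to 10.9 (without mouse 44) with mice left out, 1.92 without mouse 9; Htr3b (-2.18) was at 0.13 in edgeR. GastG against GastP gave 0.0107 with no filter, 0.0472 up to mouse 39, 0.220 without the 4 mice, and 0 to 0.118 (without GastP mouse 44; 0.00787 without GastG mouse 7 or 43). IntL (5.51) gave 8.43 in edgeR, 1.18 with the glia term, 8.80 without the 4 mice, and 0.842 (without IntL mouse 33) to 6.33, 2.74 without mouse 34. The Int codes (9.85) gave 6.28 with weights, 3.11 with the glia term, 16.2 without the 4 mice, and 4.33 (without IntP mouse 17) to 13.5, with 4.37 and 6.10 without IntL mouse 33 or 34 and 4.80 and 4.65 without IntP mouse 11 or 16. Beyond fewer mice or genes, the cause was not tested.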

Other observations

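The splits below were set beforehand; other values carry no test.

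Port cells came from many matched types: cluster 6 held 21.4% ± 9.56 (SD, 8 mice) of them, cluster 19 14.5% ± 13.5 and cluster 13 12.1% ± 10.1. Cluster 2, led by Cxcl10 and Rtp1, held 13.2% ± 5.24 of IntL and 5.89% ± 4.54 of Port cells (means of mice and SD). Its 10x neurons were rich in the satellite glia marker Fabp7, at a CPM of 1181 against 28.7 in cluster 10, also led by Rtp1. Whether glial RNA in the IntL cells led to their match with cluster 2 was not tested. IntL also held cluster 17, led by Camkv and Trpa1, at 11.8% ± 5.24 and cluster 12, led by Moxd1, at 9.03% ± 9.39 (18.8% in mouse 33 and 0% in mouse 39). In IntM, clusters 0 (led by Uts2b) and 1 (led by Efcab6) held 13.2% ± 5.80 and 14.6% ± 12.8 (cluster 1: 29.4% in mouse 26, and 6.67% and 7.69% in mice 15 and 20).

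The 53 cells coded na came from mice 31, 32, 36 and 37. Htr3a was found in 15 of 15, 8 of 8, 11 of 15 and 11 of 15 of their cells, Th in 10, 6, 13 and 12, and Sprr1a in 0 of each. Cluster 13 was fullest in mice 31 (26.7%) and 32 (62.5%), and cluster 6 in mice 36 (3 of 15 cells) and 37 (6 of 15). Glp1r was found in 4, 1, 4 and 1 of their cells.

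Other splits of the same mice were fitted to see whether chance could give as many genes. For Gast against Int, 1 of 100 splits, the real one, gave 1878 genes and the highest other gave 63. For the Int codes, 1 of 100 gave 1252 and the highest other 905. Each share is 0.01, the smallest that 100 splits can give. Those splits argue against chance in both comparisons but are too few to exclude it. They do not test the order of the mice. For Port, 2 of 100 gave 635 or more; the other reached 1231 and grouped Port mice 21, 22, 27 and 51 with Gast mice 9, 41, 42 and 44, which points to a structure of the samples. Port mice 21, 22 and 27 and GastP mouse 44 are those of high injury transcripts, without which the real comparison gave 1.08% of genes; what the others share with them was not tested. For IntL, 2 of 100 gave 701 or more; the other reached 1974 by setting IntP mice 11, 16 and 17 apart, which points to a structure of the Int mice. For GastG against GastP the real value is 0, so all 56 splits give as many by construction and decide nothing; the highest other gave 3.10% of genes.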
